A study of Homo sapiens with 4 samples.

How the data were processed

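Total RNA from Jurkat T cells was measured on 4 Illumina arrays of 1 colour, 2 of control cells and 2 of cells over-expressing PHF11myc. Per the labels, RNA was extracted with an Ambion kit, checked on an Agilent Bioanalyser and turned into biotinylated cRNA. Groups and replicate numbers were taken from the titles of the samples. The software, background step and genome build that the authors used are not given in the sources used here, so no coordinates are printed.

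The main values were the deposited non-normalized intensity values, 1 average bead signal per probe and array, named as such per the file headers. They were linear, and the lowest on each array lay between 60.6 and 67.4, so the scanner background was still in them. The table held 22177 probes with a symbol each and no detection p-values. Whether a probe was above background could therefore not be judged, and the planned neqc normalization, which uses those p-values, gave way to the fallback fixed with it. A deposited value matrix held background-subtracted intensity values of the same arrays, linear and not centred per gene, with a median of 43.5 in each column and 17.9% to 18% of values below 0. Set against the scanner values in sorted order, its control replicate 1 column differed by a constant 97.2 (range of the difference 0.013), while the other columns differed by varying amounts, so that array had been the target of the scaling. The method of that scaling stays unknown. Its row identifiers had no match in the other table, so it served only as an alternative at the level of unnamed probes.

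In the main setting, signals were corrected with limma's normexp (offset 50), quantile normalized and put on the log2 scale. The offset compresses the changes of dim probes, so their differences are understated. Symbols were updated through a table of RefSeq genes of the assembly GRCh38.p14, used only for names and for which genes neighbour each other. Of 18190 symbols, 13336 were current, 3241 had 1 current name, 386 matched through a gene ID, 179 were older names of several genes and were kept, and 1028 were kept without a match. Another 20, on 29 probes, had been turned into dates by a spreadsheet and were left unnamed. A symbol that is current can still have meant another gene when the array was designed, and 822 were also older names of another gene. Probes whose mean over the 4 arrays was below the median over all probes (6.97 on the log2 scale) were left out. A gene was tested through its brightest probe, which left 10089 genes, 16 unnamed probes included, of which 4 changed. Among 141 other tested probes of changed genes, 110 (78%) had the same sign, 43 of them also past the threshold, and 2 were past it in the opposite direction, in RPL13 and SLC39A3.

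Differences (PHF11myc minus control, log2) were tested two-sided with limma's lmFit and eBayes, adjusted by Benjamini-Hochberg over the genes tested, at adjusted p under 0.05. With 2 residual degrees of freedom per gene, the test leaned on a prior of 23.2 degrees of freedom and an SD of 0.11 estimated over all genes. The number of arrays limits the precision. For 35 gene lists of 1129 entries, camera (correlation preset at 0.01) was run over the tested members, with camera at an estimated correlation, camera on ranks, fry and Fisher's exact test of the share changed beside it. A list's counts were also taken with p-values adjusted over the list alone. In the lists, 39 genes belong to several. The tests were tried on 20 simulated sets of 10089 genes with the arrays' means and spread, 200 genes changed in each and independent noise. Of changes of 0.5 on the log2 scale 51.7% were recovered and of changes of 1, 2 and 3 all 100%, with 4.22% false among the calls. With no change simulated, limma made 0 calls on average and camera called 0 lists. The simulated spread followed the test's own prior and no genes were correlated, so low rates of false calls were largely set in advance. They do not measure false calls on the real arrays.

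The groups, the tests of genes and lists, the gene lists, alternatives and the rule for named genes were set before the data were examined. Some tests of explanations in the closing section were chosen later, as said there. The rule took PHF11, the 10 largest rises and 10 largest falls past the threshold whose groups do not overlap, and in each list up to 4 members past the threshold by size (else those of largest change, as values) and up to 2 of the most abundant. Y-linked genes and XIST were left out of it, and genes named beyond it are said to be. Some genes that it picked are not reported here. The alternatives were the deposited matrix, no background correction, an offset of 16, median scaling, cyclic loess, the replicate number as a block, leaving out each array, no filter, the probes above the 75th percentile of signal, the mean of a gene's probes, every probe on its own, an intensity trend or robust prior in eBayes, and stricter thresholds. Leaving out an array left 1 in its group, which was assumed to vary like the other group. Work was done in R 4.3.3 with limma 3.58.1, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.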

Results

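RNA from Jurkat cells, an established human T-cell leukaemia line, was measured on 4 Illumina expression arrays of 1 colour. The control group had 2 arrays and the group over-expressing PHF11myc, a tagged form of the PHD finger protein PHF11, also had 2. The title of the series names the question as the part that PHF11, a gene linked to atopy, plays in T-cell activation and viability. Median raw signals over 22177 probes were 141 and 168 in the controls and 134 and 143 in PHF11myc, with the lowest signals on each array between 60.6 and 67.4. After normalization and a filter on dim probes, 10089 genes were tested. The labels do not say that the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Nor do they say how many separately made cell populations each group held, so a difference between the populations was not separated from one due to PHF11myc.

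PHF11myc cells differed from control cells in 1349 of the 10089 genes (13.4%; limma, Benjamini-Hochberg adjusted p under 0.05), of which 679 were higher and 670 lower. Genes of DNA replication, of mitosis, of the GIMAP family and of thymocyte stages shifted upward as lists, and genes of cholesterol synthesis, of the unfolded protein response and of heat shock shifted downward. These 7 of the 35 lists passed limma's camera test with its preset correlation (adjusted p 0.00015 to 0.034). Of them, the replication, mitosis and cholesterol lists kept their call when any 1 array was left out. None passed with an estimated correlation. That form rests on only 2 residual degrees of freedom, so a pass was hardly possible and its failures decide little. Fry, which asks whether a list's genes move 1 way on balance, passed the replication genes only (adjusted p = 0.00458). Camera on ranks passed 5 of the 7, all but the GIMAP (adjusted p = 0.193) and thymocyte lists (0.332). GPR183, a receptor that guides lymphocyte migration, rose the most, by 6.31-fold, and IFTAP, which encodes a protein associated with intraflagellar transport, fell the most, by 6.48-fold. The PHF11myc mean of IFTAP lay under the cutoff of the filter on dim probes, so the size of its fall is uncertain. CD2, an adhesion and costimulatory receptor of T cells, fell by 3.3-fold. Most changes were small: the median size among the changed genes was 0.44 on the log2 scale, and 45 rises and 36 falls reached 2-fold. With each array scaled to its median in place of quantile normalization, 633 genes passed, 199 higher and 434 lower, so that 31.4% of calls were rises against 50.3%. This scaling ended the calls of 38 of the 196 genes picked by the naming rule, among them RFC3, E2F2, AURKB, CALR, CTH and IFI30. Leaving out any 1 array lowered the count, and most genes called then were among the 1349. Without control replicate 2 a larger part of the calls lay outside the 1349 than without any other array.

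**Figure D1:**
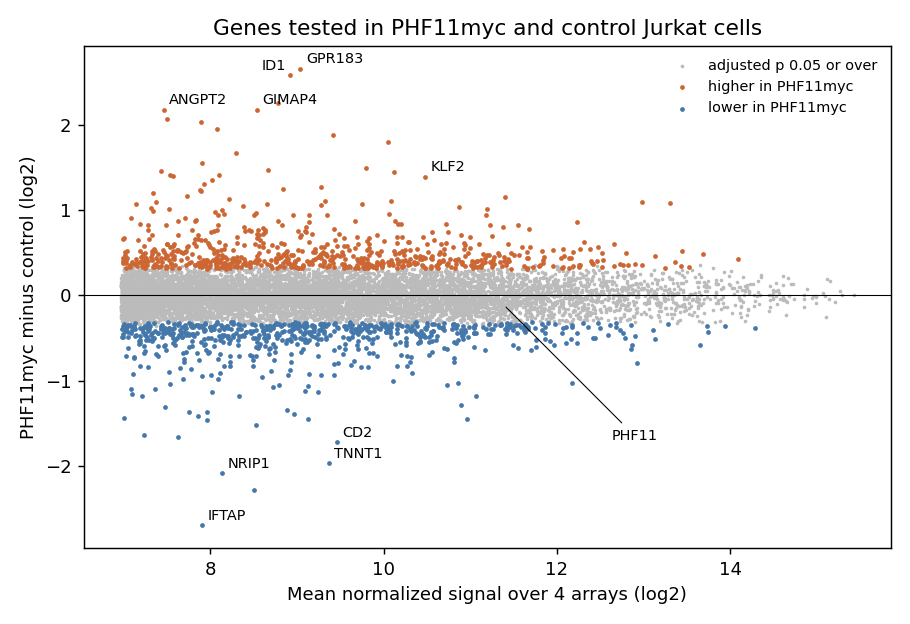
Change of each tested gene (PHF11myc minus control, log2) against its mean normalized signal over the 4 arrays (log2). Unnamed probes, Y-linked genes and XIST are not drawn. The genes drawn of the 679 higher (orange) and 670 lower (blue) lie on both sides of 0 at all but the highest signals. PHF11 lies among the genes not past the threshold (grey).

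The 10 largest rises after the moderated test spanned 1.80 to 2.66 on the log2 scale, with standard errors of 0.11 to 0.12. GPR183 (array symbol EBI2) went from 7.71 ± 0.17 (SD, n = 2) in the controls to 10.37 ± 0.06 (SD, n = 2) in PHF11myc, a difference of 2.66 ± 0.11 (SE; adjusted p = 3.5e-15). ID1, an inhibitor of basic helix-loop-helix transcription factors, went from 7.63 ± 0.12 to 10.21 ± 0.16 (SD, n = 2 each; adjusted p = 6.04e-15). GIMAP4, a GTPase of lymphocytes, and ANGPT2, a ligand of the TIE2 receptor, each rose by 2.18. MAGEH1, of the melanoma antigen family, rose by 2.07, SCG2, a secretogranin, by 2.03 and DTNA, a dystrobrevin, by 1.96. Control means of ANGPT2 (6.37), MAGEH1 (6.47) and SCG2 (6.88) lay under the dim-probe cutoff of 6.97. The sizes of these rises moved with the processing, for ANGPT2 from 1.93 to 2.81 over the settings tried. The matrix gene FBLN2 rose by 1.80. The scaffold protein gene AHNAK rose by 1.88 through its brightest probe and by 0.46 through its other tested probe, with 1.17 for the mean of its probes. The remaining gene, PRG1 under its array symbol, rose by 2.26, but that symbol is also an older name of SRGN, IER3 and PLPPR4, so its identity was not settled. The symbol SCG2 is likewise also an older name of MEN1.

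The 10 largest falls spanned 1.45 to 2.70 on the log2 scale. IFTAP (array symbol LOC119710) went from 9.26 ± 0.00 in the controls to 6.56 ± 0.12 in PHF11myc (SD, n = 2 each; adjusted p = 2.46e-15). That PHF11myc mean, like those of DLL1 (6.79) and GRB10 (6.41), lay under the dim-probe cutoff of 6.97. The sizes of these falls moved with the processing, for IFTAP from -2.46 to -3.26 over the settings tried. NRIP1, a corepressor of nuclear receptors, fell by 2.09 and TNNT1, a troponin of slow skeletal muscle, by 1.97. CD2 went from 10.32 ± 0.07 to 8.60 ± 0.09 (SD, n = 2 each; adjusted p = 7.33e-12). The Notch ligand gene DLL1 fell by 1.66, the nuclear receptor gene RORB by 1.51, the interferon-stimulated gene IFI44 by 1.46 and RGS16, a regulator of G-protein signalling, by 1.45. GRB10, an adaptor of receptor tyrosine kinases, fell by 1.64 through its brightest probe, while its other tested probe gave -0.13 (adjusted p = 0.502) and the mean of its probes -0.88. Each of the genes named in this paragraph and the one before stayed past the threshold in the same direction when any 1 array was left out.

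**Figure D2:**
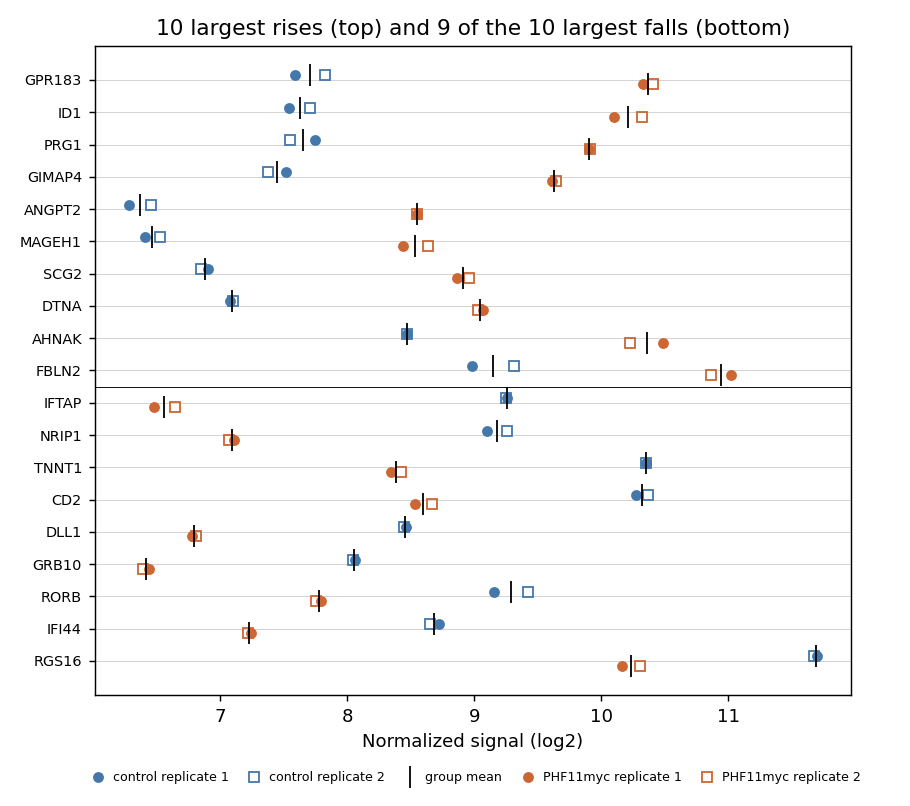
Normalized signal (log2) on each of the 4 arrays for the 10 largest rises (top) and 9 of the 10 largest falls (bottom), with filled circles for replicate 1, open squares for replicate 2 and bars for group means. As the naming rule required, both PHF11myc arrays of every gene lie on one side of both control arrays, as for GPR183 with means of 7.71 and 10.37.

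The array's PHF11 probe lies, per the labels, in a 3′ part of the cDNA that the construct does not carry. It therefore read the cell's own transcript and checked nothing about over-expression. Its normalized log2 signals were 11.54 and 11.34 in the controls and 11.35 and 11.31 in PHF11myc, a change of -0.11 ± 0.11 (SE; adjusted p = 0.576).

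Among 32 tested genes of the T-cell receptor complex and its proximal signalling, 9 fell, 3 rose and 20 did not pass (11 lower and 7 higher adjusted over the list alone). Besides CD2, the falls included THEMIS, a regulator of thymocyte selection (-0.78), UBASH3B, a phosphatase that restrains receptor signalling (-0.67), and the adaptor gene LCP2, also called SLP-76 (-0.54). The rises were CD3E (0.34) and CD3G (0.43), parts of the receptor complex, and the phosphatase gene PTPN22 (0.38), which were picked out after their values were seen. CD247, the zeta chain and the most abundant member, gave 0.23 without passing the test (adjusted p = 0.159). As a list these genes did not pass by camera (median -0.12, adjusted p = 0.0631), by camera on ranks (0.241) or by fry (0.0646). By camera the list did pass with median scaling (0.0287), with the replicate number as a block (0.0257) and with no filter on dim probes (0.0193). It also passed among the probes above the 75th percentile of signal (0.0327). Its mean change of -0.15 was -0.14 without PHF11myc replicate 1 and -0.16 without PHF11myc replicate 2. In both of these the list also passed by camera, though 1 array alone then stood for PHF11myc. The 4 omissions, in the order control replicates 1 and 2 and PHF11myc replicates 1 and 2, left 6, 7, 7 and 5 members lower and 1, 1, 0 and 0 higher, and median scaling left 8 lower and 0 higher.

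Of 14 costimulatory and inhibitory receptors, 2 rose and 4 fell, the same counts as adjusted over the list alone (list adjusted p = 0.388). CD28, which gives the main costimulatory signal of T cells, rose by 0.89 ± 0.11 (SE), while LY9, a receptor of the SLAM family, fell by 1.42 ± 0.11 and CD96 by 0.58 ± 0.11. Both tested LY9 probes gave a fall, of 1.42 and 1.35. The 21 activation-induced genes held 1 rise and 4 falls (1 and 5 adjusted over the list alone; list adjusted p = 0.177), among them CD69, an early surface marker of activation (-0.63), and SPRY1, a feedback inhibitor of receptor kinases (-0.59). MYC, one of the most abundant of them, gave -0.17 (adjusted p = 0.33). Regulators and cytokines of Th1 and Th2 cells, with 19 tested, had 2 rises and 2 falls (3 and 3 adjusted over the list alone; list adjusted p = 0.969). STAT5A, a transducer of cytokine signals, rose by 1.13 and the receptor gene TGFBR2 fell by 1.14. In the NF-kappa-B list of 19 genes, 2 rose and 3 fell (2 and 5 adjusted over the list alone; list adjusted p = 0.572), with NFKB1 lower by -0.58 and CFLAR higher by 0.62. Without control replicate 1 the falls numbered 2 among the receptors, 2 among the activation genes and 1 in the NF-kappa-B list. There was 1 fall in the NF-kappa-B list without each of the other arrays too, and 2 among the receptors without PHF11myc replicate 2. Rises in the activation list went to 0 without control replicate 1 or either PHF11myc array, and in the NF-kappa-B list to 1 without control replicate 1, control replicate 2 or PHF11myc replicate 1. Without control replicate 1 there was 1 rise in the Th1 and Th2 list. With median scaling, rises and falls were 1 and 4 among the receptors, 0 and 3 among the activation genes, 1 and 2 in the Th1 and Th2 list and 1 and 1 in the NF-kappa-B list.

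Thymocyte stage genes shifted upward, with 11 of 30 higher, 2 lower and 17 not past the threshold (12 higher and 6 lower adjusted over the list alone; median 0.07, mean 0.18, camera adjusted p = 0.0303). DTX1 and HES4, both targets of Notch signalling, rose by 1.41 ± 0.11 and 1.09 ± 0.11 (SE), and CD1B, a surface marker of cortical thymocytes, rose by 0.94 ± 0.11. LMO2, a factor of early progenitors and of T-cell leukaemia, fell by 1.16 ± 0.11. The most abundant members, MYB and LEF1, gave 0.13 and -0.22 and did not pass (adjusted p = 0.494 and 0.194). The 6 tested GIMAP genes, which encode GTPases of lymphocyte survival, included 2 rises, GIMAP4 and GIMAP7 (0.72), and 4 genes that did not pass (2 higher and 1 lower adjusted over the list alone; median 0.21, camera adjusted p = 0.00876). With an estimated correlation each list gave adjusted p = 0.529. The thymocyte call was lost without control replicate 1 (adjusted p = 0.152), without control replicate 2 (0.117), with a background offset of 16 (0.0639) and on ranks (0.332). The GIMAP call was lost without control replicate 2 (0.117) and on ranks (0.193). With median scaling 8 thymocyte genes rose and 2 fell.

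Genes of the cell cycle shifted upward by small amounts. In the list of G1/S and DNA replication genes, 10 of 51 rose, 1 fell and 40 did not pass (17 and 1 adjusted over the list alone), with a median of 0.18 and a camera adjusted p of 0.00015. RB1, which restrains entry into S phase, rose by 0.66 ± 0.11 (SE), and CDK6, a kinase that drives that entry, fell by 0.58 ± 0.11 and was the fall in the list. The replication factor gene RFC3 rose by 0.51 and the transcription factor gene E2F2 by 0.50, but RFC3 was not past the threshold without control replicate 1 (adjusted p = 0.0537), nor E2F2 without control replicate 1 (0.14) or PHF11myc replicate 1 (0.186). The other tested probes of RFC3 gave 0.41 and 0.07. Among 48 G2/M genes, 7 rose, 1 fell and 40 did not pass (8 and 1 adjusted over the list alone; median 0.13, camera adjusted p = 0.00375). BUB1, a kinase of the spindle checkpoint, rose by 0.57 ± 0.11. AURKB, a mitotic kinase, rose by 0.48, though not past the threshold without control replicate 1 (adjusted p = 0.0651) or PHF11myc replicate 2 (0.0716). The abundant CCND3, MCM7 and CDC20 gave 0.11, -0.12 and 0.05 without passing. Both list calls held when any 1 array was left out, and both lists had adjusted p = 0.529 with an estimated correlation. Without control replicates 1 and 2 and PHF11myc replicates 1 and 2, in that order, 2, 6, 2 and 4 of the replication genes and 1, 9, 5 and 2 of the G2/M genes rose, and with median scaling 1 of each did. The G2/M fall was SGO1 (-0.46), which was lost without control replicate 1 (adjusted p = 0.129) or PHF11myc replicate 1 (0.154). Of 15 CDK inhibitors and quiescence genes, 1 rose and 3 fell (3 and 5 adjusted over the list alone; list adjusted p = 0.982). The rise was KLF2, a factor of T-cell quiescence, by 1.39 ± 0.11 (SE), while TXNIP, an abundant member, gave -0.29 (adjusted p = 0.0674). Those falls numbered 0, 1, 1 and 0 under the same omissions and 1 with median scaling.

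Of 31 pro-apoptotic genes, 4 rose and 5 fell (5 and 6 adjusted over the list alone; list adjusted p = 0.825). TNFSF10, the death ligand TRAIL, rose by 0.66 and its receptor gene TNFRSF10B fell by 0.47, but neither passed without control replicate 1 (adjusted p = 0.0513 and 0.0575). Among 18 anti-apoptotic genes, 3 rose and 15 did not pass, also when adjusted over the list alone (list adjusted p = 0.615). CFLAR, an inhibitor of caspase 8, rose by 0.62 ± 0.11 (SE). The other 2, BIRC5 (0.39) and PIM1 (0.34), did not hold: BIRC5 lost its call without control replicate 1 or either PHF11myc array (adjusted p 0.0758 to 0.169) and PIM1 under each of the 4 omissions (0.0573 to 0.413). Targets of p53 numbered 22, with 2 higher and 5 lower, also when adjusted over the list alone (list adjusted p = 0.388), among them GADD45A, a gene of growth arrest (-0.68). TP53I3 gave -0.71 through its brightest probe and 0.10 through another (adjusted p = 0.663). Without control replicates 1 and 2 and PHF11myc replicates 1 and 2, in that order, the pro-apoptotic list had 1, 4, 2 and 1 rises and 0, 5, 2 and 2 falls, and the p53 list 0, 1, 1 and 1 rises and 2, 4, 3 and 3 falls. Anti-apoptotic rises were 1, 2, 1 and 1. With median scaling, rises and falls were 1 and 4 in the pro-apoptotic list, 1 and 0 in the anti-apoptotic list and 0 and 4 in the p53 list.

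Genes of cholesterol synthesis and uptake fell: 9 of 30 were lower and 21 did not pass (15 lower adjusted over the list alone; median -0.21, camera adjusted p = 0.00244). CYP51A1 and HMGCS1, enzymes of the pathway, fell by 0.80 ± 0.11 and 0.58 ± 0.11 (SE). The list's call held when any 1 array was left out, with 4, 10, 3 and 4 members lower without control replicates 1 and 2 and PHF11myc replicates 1 and 2, in that order, and 7 with median scaling. It gave adjusted p = 0.529 with an estimated correlation.

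Lists of chaperone genes also shifted downward. In the list of the unfolded protein response and endoplasmic reticulum chaperones, 7 of 23 fell, 2 rose and 14 did not pass (8 and 2 adjusted over the list alone; median -0.17, camera adjusted p = 0.034). The chaperone gene CANX fell by 0.68 ± 0.11 (SE) and EDEM1, of the degradation of misfolded proteins, by 0.56 ± 0.11. One of the rises was ERN1, the stress sensor IRE1 (0.72 through its brightest probe and 0.05 through another, adjusted p = 0.869), and the other was CALR, a chaperone (0.48), whose call was lost without control replicate 2 (0.0572). Heat shock genes had 2 of 19 lower, HSPA4 (-0.40) and HSPA4L (-0.39), and 17 not past the threshold (3 lower adjusted over the list alone; median -0.23, camera adjusted p = 0.0159). The abundant HSPA8 and HSP90AA1 gave -0.30 and -0.31 (adjusted p = 0.104 and 0.0549). The other tested probe of HSPA8 passed (-0.33, adjusted p = 0.041), while that of HSP90AA1 gave 0.07 (adjusted p = 0.746). Both lists had adjusted p = 0.529 with an estimated correlation. The unfolded protein response call was lost without control replicate 2 (adjusted p = 0.135), PHF11myc replicate 1 (0.0813) or PHF11myc replicate 2 (0.14) and with the replicate number as a block (0.0802), and the heat shock call without control replicate 2 (0.117) or PHF11myc replicate 2 (0.0565). Without control replicates 1 and 2 and PHF11myc replicates 1 and 2, in that order, the members lower were 3, 4, 3 and 2 in the first list and 1, 1, 0 and 1 in the second; with median scaling they were 4, with 1 rise, and 2. HSPA4 gave 0.08 through its other tested probe (adjusted p = 0.705) and -0.16 as the mean of its probes, which ended its call (0.379). It also lost its call without either control array or PHF11myc replicate 1 (adjusted p 0.0696 to 0.275), and HSPA4L without control replicate 1 or either PHF11myc array (0.0875 to 0.178).

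**Figure D3:**
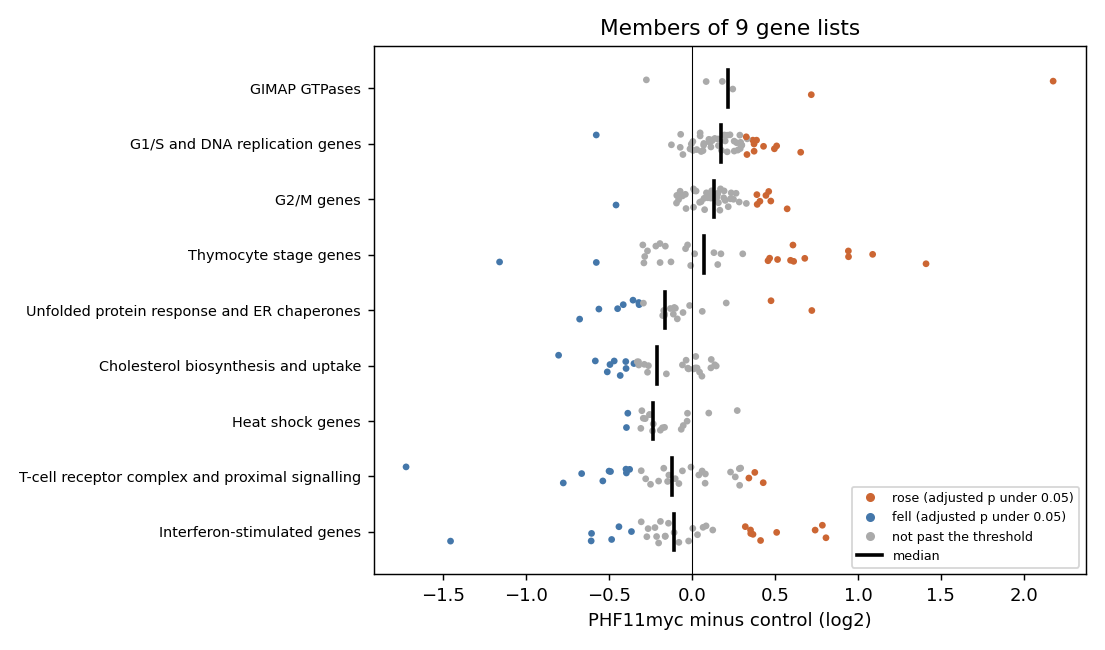
Change of each tested member (PHF11myc minus control, log2) in the 7 gene lists past the threshold and in the T-cell receptor and interferon lists, with members that rose in orange, members that fell in blue, the rest in grey and the median as a black bar. Medians run from 0.21 for the GIMAP genes to -0.23 for the heat shock genes.

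Other lists of metabolism and stress did not pass. Among 35 genes of glycolysis and the hypoxia response, 2 rose and 5 fell (2 and 7 adjusted over the list alone; list adjusted p = 0.077, and 0.0263 with no filter on dim probes), with the glucose transporter gene SLC2A3 lower by 2-fold. Of 32 ATF4 targets, 2 rose and 5 fell (2 and 7 adjusted over the list alone; list adjusted p = 0.204); CTH, an enzyme of cysteine synthesis, rose by 0.51. The 27 oxidative stress and metallothionein genes had 4 rises and 4 falls (4 and 5 adjusted over the list alone; list adjusted p = 0.923). The metal-binding MT2A rose by 0.94, as did MT1A, a gene with near-identical relatives, by 0.61, and OSGIN1 fell by 0.84. Oxidative phosphorylation had 4 rises among 56 genes (1 adjusted over the list alone; list adjusted p = 0.294), and the abundant ATP5F1B gave -0.04. Without control replicates 1 and 2 and PHF11myc replicates 1 and 2, in that order, falls were 2, 1, 2 and 2 in glycolysis, 1, 4, 0 and 2 among ATF4 targets and 2, 3, 1 and 2 in oxidative stress, and rises in oxidative phosphorylation 0, 4, 0 and 1. Rises in the first 3 lists were then 1, 1, 0 and 0, then 1, 2, 1 and 1, then 2, 4, 4 and 2, and oxidative phosphorylation had 2 falls without PHF11myc replicate 2. With median scaling, rises and falls were 0 and 3 in glycolysis, 1 and 2 among ATF4 targets, 2 and 2 in oxidative stress and 1 and 0 in oxidative phosphorylation.

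Interferon-stimulated genes changed in both directions. Of 33 tested, 9 rose, 6 fell and 18 did not pass (9 and 9 adjusted over the list alone), and the list had no net shift past the threshold (median -0.11, camera adjusted p = 0.643). EPSTI1, OAS2 and IFITM1 rose by 0.81, 0.79 and 0.74, all 3 induced by interferon, against the fall of IFI44 by 1.46; the other tested probe of OAS2 gave 0.40. ADAR, an abundant member, gave -0.14 (adjusted p = 0.436). The share changed, 45.5%, was higher than that of the other tested genes by Fisher's exact test (adjusted p = 0.000246). That test, which disregards the correlation between genes, also passed for thymocyte (43.3% changed, adjusted p = 0.000945), T-cell receptor (37.5%, 0.00618), unfolded protein response (39.1%, 0.0163) and costimulatory genes (42.9%, 0.0456). Without control replicates 1 and 2 and PHF11myc replicates 1 and 2, in that order, 3, 7, 3 and 5 interferon genes rose and 4, 5, 4 and 5 fell, and with median scaling 3 rose and 4 fell.

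Of 18 genes of MHC class I presentation, 2 rose and 3 fell, also when adjusted over the list alone (list adjusted p = 0.955), and the median (-0.01) differed in sign from the mean (0.00) and the test. CANX was the largest of the falls, and the abundant B2M gave -0.01. Among 8 MHC class II genes, 1 rose and 1 fell (1 and 2 adjusted over the list alone; list adjusted p = 0.982). IFI30, a thiol reductase of antigen processing, was the rise (0.51), and was not past the threshold without control replicate 1 (adjusted p = 0.0569) or PHF11myc replicate 1 (0.07). The fall, HLA-DMB (-0.37), was lost under each omission (adjusted p 0.0537 to 0.21). Chemokine receptors, integrins and migration genes had 5 rises and 3 falls among 26 (5 and 5 adjusted over the list alone; list adjusted p = 0.666). MSN, which links actin to the membrane, fell by 0.58 ± 0.11 (SE), and CXCR4, the receptor of CXCL12, rose by 0.53 but not past the threshold without control replicate 1 (adjusted p = 0.0715). Rises among the migration genes numbered 0, 3, 2 and 1 without control replicates 1 and 2 and PHF11myc replicates 1 and 2, in that order, and falls 1, 3, 1 and 3. Under the same omissions class I falls were 2, 1, 1 and 2, and each left 1 rise. With median scaling, rises and falls were 1 and 2 among the migration genes, 0 and 2 in class I and 0 and 0 in class II.

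Among 72 cytosolic ribosomal protein genes, 10 rose and 1 fell, also when adjusted over the list alone (median 0.02, list adjusted p = 0.175). The rise of RPL13 (0.54) rested on its brightest probe, against -0.44 through another, and was lost without control replicate 1 (adjusted p = 0.0506). The abundant RPL6 and RPS29 did not pass through their brightest probes, but dimmer probes gave -0.38 and 0.43 (adjusted p = 0.0203 and 0.00962). Of the 72, 3, 5, 3 and 4 rose without control replicates 1 and 2 and PHF11myc replicates 1 and 2, in that order, and 0 with median scaling, and the fall was lost in all but the second. The list passed by camera with median scaling (adjusted p = 0.000248) and with cyclic loess (0.00347). Those calls use the preset correlation of 0.01, while the correlation estimated for this list in the main setting was 0.11. In that setting it did not pass by camera on ranks (adjusted p = 0.207) or by fry (0.294). Its mean change of 0.06 was 0.10 without control replicate 1, where the list also passed by camera at the preset correlation with 1 control array left. Ribosome biogenesis had 0 of 30 genes changed by limma, with 4 at an unadjusted p under 0.05, and 0 adjusted over the list alone (list adjusted p = 0.666). It had 1 rise without control replicate 2. Replication-dependent histone genes had 2 rises among 11 (3 adjusted over the list alone; list adjusted p = 0.116), of which H2AC18 (array symbol HIST2H2AA) rose by 0.68 and has near-identical copies. Without PHF11myc replicate 1 or with median scaling it was 1 rise. In the list of PHD finger genes and histone methyltransferases, to which PHF11 belongs by family, 1 of 32 passed, PHF19 (-0.35), whose other probes gave 0.23 and 0.07 (0 adjusted over the list alone; list adjusted p = 0.825). Its call was lost without control replicate 2 (adjusted p = 0.214), PHF11myc replicate 1 (0.205) or PHF11myc replicate 2 (0.19). Among 9 tested genes that lie near PHF11, RCBTB2 rose by 1.66 ± 0.11 (SE) and 8 did not pass, also when adjusted over the list alone (list adjusted p = 0.128, but 0.0264 without PHF11myc replicate 1 and 0.0353 with the replicate number as a block). RB1, which is not in that list, lies in the same region and rose by 0.66. Of 18 commonly used reference genes, RPL13A passed (0.36; 0 adjusted over the list alone; list adjusted p = 0.39), and EEF1A1 and TUBA1B gave 0.05 and 0.17. RPL13A was not past the threshold without control replicate 2 (adjusted p = 0.192), PHF11myc replicate 1 (0.179) or PHF11myc replicate 2 (0.156).

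Marker lists of other cell types gave few calls, and none passed as a list. The B-cell list had 1 fall among 5 genes (CD79A, -0.37; list adjusted p = 0.887), the NK and cytotoxic list 1 among 6 (GZMA, -0.44; 0.267), and the epithelial and fibroblast list 1 among 5 (TAGLN, -0.39; 0.267). Of 6 myeloid genes, CTSG, a protease of granulocytes, rose by 1.10 ± 0.11 (SE) and CD68 fell by 0.45 (list adjusted p = 0.39). ITGA2B, an integrin of platelets, rose by 0.60 among 8 erythroid and megakaryocyte genes (list adjusted p = 0.267). Counts adjusted over the list alone were the same in these 5 lists. The epithelial gene KRT18 gave 0.02 through the probe used and -0.54 through another of similar signal (adjusted p = 0.000902). The calls of CD79A, GZMA and TAGLN were lost without control replicate 1, PHF11myc replicate 1 or PHF11myc replicate 2 (adjusted p 0.0511 to 0.229), that of CD79A also with the mean of its probes (0.0967), its other probe giving -0.16, and that of CD68 without control replicate 1 or PHF11myc replicate 2 (0.107 and 0.161). Median scaling left 0 calls in the B-cell list and 0 in the epithelial and fibroblast list.

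Arrays of a group were nearer to each other than to those of the other group. Over the tested genes, the SD of log2 differences was 0.18 within the controls and 0.14 within PHF11myc, against 0.27 to 0.30 for the 4 pairs between groups, a mean ratio of 1.76. Both arrays of each group lay on one side of both of the other in 54.4% of the tested genes, against 33.3% by chance. No raw signal was identical between any 2 arrays. The 2 other ways of dividing the 4 arrays into pairs gave 0 genes past the threshold each by limma, with 90 and 33 at an unadjusted p under 0.05, against 1349 and 2671 for the real groups. Low counts were to be expected there, since the group difference then adds to the spread within each side, and 3 divisions are too few for a test of chance.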

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

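Between 971 and 1743 genes passed with the deposited matrix (1306 unnamed probes), no background correction, an offset of 16, cyclic loess, no filter, the mean of a gene's probes, every probe on its own, and a trend or robust prior, and with the replicate number as a block. The count fell to 633 (199 higher, 434 lower) with median scaling, under which the median over all genes was -0.07, and the cause was not tested. It fell to 832 (417 and 415) in the probes above the 75th percentile of signal, where 5346 genes were tested, to 731 (362 and 369) at adjusted p 0.01 and to 81 (45 and 36) with a 2-fold minimum, by construction. Leaving out 1 array gave 570 to 1034 genes (274 to 528 higher, 296 to 506 lower), from fewer samples. List calls, 7 in the main setting, numbered 3 (without control replicate 2) to 8 (without PHF11myc replicate 1) when an array was left out, 9 with median scaling and with no filter, 8 with cyclic loess, 6 with an offset of 16, 5 with camera on ranks, 1 with fry and 0 by camera with an estimated correlation, which gave 1 list at an unadjusted p under 0.05; only 2 residual degrees of freedom support that estimate. For the replication genes the estimated correlation (-0.02) was below the preset 0.01, yet the unadjusted camera p went from 4.27e-06 to 0.0301. That loss therefore did not come from correlation between the genes. The ratio of differences between and within groups went from 1.76 to 1.39 over all probes with no filter, where the cause was not tested. The change of PHF11 stayed between -0.21 and -0.01 and short of the threshold (adjusted p 0.206 to 0.968) in 14 alternatives. Of 196 genes picked by the naming rule, 0 changed direction while called, 124 kept their side of the threshold throughout and 72 crossed it in at least 1 alternative. Lists and PHF11 were not run on the deposited matrix, whose rows carry no names here.

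The series speaks of paired samples without saying what a pair shares. Same-numbered arrays deviated together only weakly (r = 0.0963 across genes), and with 2 pairs the arrays were taken to share only a number. With the replicate block, 1743 genes passed (864 higher, 879 lower), among them all 1349, and 8 lists, with the T-cell receptor list (adjusted p = 0.0257) and the list of genes near PHF11 (0.0353) added and the unfolded protein response list (0.0802) lost. With no detection p-values, signal over background sets a limit that could not be measured.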

Other observations

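Outside the fixed lists, genes best known from other tissues were among the changes of 2-fold or more; they were picked out after their values were seen. FGFR3, a fibroblast growth factor receptor, rose by 1.44 ± 0.11 (SE), POU3F2, a factor of neural development, by 1.47, PPARG, the regulator of fat cell differentiation, by 1.24, and the gap junction gene GJB2 by 1.35. MSRB3, a methionine sulfoxide reductase, rose by 1.56, the kinase gene NUAK1 by 1.46 and the metallothionein gene MT3 by 1.42. YAP1, the effector of the Hippo pathway, fell by 1.37 ± 0.11 (SE), FERMT2, an activator of integrins, by 1.34, the von Willebrand factor gene VWF by 1.17 and ABLIM1, which binds actin, by 1.39. PPP1R15A, which reverses the stress block of translation, fell by 1.29. None of these was tested as a group.

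Genes of the Notch pathway were also seen on both sides, again picked out after their values were known and not tested as a group. The receptor gene NOTCH1 rose by 0.61 and the targets HES1, HES4 and DTX1 by 0.94, 1.09 and 1.41, while the ligand gene DLL1 fell by 1.66.

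The tests on array brightness, on a local copy number gain and on list changes with 1 array left out were chosen only after the results were seen. The first pattern was the number of changed genes. If segments gained or lost in one cell population were the main cause, neighbouring genes would shift together, but 12.7% of 1280 changed genes with a known place (95% exact binomial interval 10.9 to 14.6) had 10 nearest tested neighbours whose median moved the same way by over 0.1. That is above the highest share in 200 shuffled gene orders (10.9%), and adjacent genes were weakly correlated (r = 0.0631 across genes, p = 0.0001, the smallest that 10000 permutations can give), so a small contribution of this kind may remain. For brightness, control replicate 1 and PHF11myc replicate 2, with medians of 141 and 143, still differed 1.63 times as much as the more distant pair within a group. Every pair between groups differed more than both pairs within, so no choice of pair could have given a ratio under 1. The test thus shows only that arrays of like median signal still differed, and does not decide what part brightness played. Among 114 families of gene symbols, 1 held more changed genes than the rest, the symbols that begin with CD, grouped by symbol alone and not all of surface molecules, with 11 of 46 higher and 8 lower (41.3% changed, Fisher adjusted p = 0.000288), CD7 (0.61) and CD1B (0.94) among the former and CD2 (-1.72) and CD96 (-0.58) among the latter, though some are also in the fixed lists. A response to PHF11myc and a difference between cell populations that arose without it stay open, since the design does not separate them.

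The second pattern was that some lists rose while others fell. If it were a change that follows signal level, lists of the same size matched on mean signal would reach their medians. In 7 of the 7 lists under 5% of 10000 matched draws did (at most 3.55%, for the thymocyte genes). The lists had been picked for their shift, and after quantile normalization the matched draws centred near 0 (mean medians -0.005 to -0.001). Low shares were thus largely fixed in advance. They show only that genes of like signal did not shift as these lists did. If 1 array stands apart and made the changes, they would largely go without it, but each of the 7 lists kept most of its mean log2 change when any 1 array was left out. The lowest share, 80.3% (95% interval over members 55.6 to 105), was that of the heat shock genes without control replicate 2. The calls were less steady: those of GIMAP, thymocyte, unfolded protein response and heat shock genes were lost without control replicate 2 (mean changes of 0.49, 0.20, -0.12 and -0.14, against 0.52, 0.18, -0.14 and -0.17), where fewer arrays support the test, and some were also lost without another array. This test replaced earlier forms. Those asked whether the group means overlapped, which the choice of lists largely fixed, and whether calls were lost, which depends on the number of arrays. The choice of lists largely fixed the share kept too, since most of a change can go only if arrays of a group differ as much as the groups do. The interval over members also leaves out what all members share on an array. The test therefore does not decide whether 1 array stands apart. A response to PHF11myc and differences in culture, such as density, stay open and were not tested.

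The third pattern was the rise of RCBTB2 (1.66) and of RB1 (0.66), an adjacent tested gene, in the region of PHF11; FNDC3A, adjacent on the other side, gave 0.17 (adjusted p = 0.33). A gain of the region in PHF11myc cells would raise the genes around them, but the 10 nearest tested neighbours of RCBTB2, RB1 left out, had a median change of 0.10 (0.0965; quartiles -0.03 and 0.16), under the bound of 0.33 set for a gain. A change in these genes alone, or a gain too small to include their neighbours, stays open. A wider gain that raises genes by less than the bound could not be detected by this test, whose bound was set after the values were seen.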
